A study of Mus musculus with 8 samples.

How the data were processed

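Splenic B cells from 4 pregnant and 4 non-pregnant mice were profiled on an expression array, with 1 array per mouse. Per the labels' protocols, C57BL/6 females were mated with BALB/c males and studied on day 14 of pregnancy, and virgin females of matched age served as controls. B cells were enriched from spleen by negative magnetic selection, in which the other cells are removed and the B cells stay unbound. Preparations had a purity above 98% by flow cytometry, and 200 ng of total RNA with an RNA integrity number of at least 7.4 was used, per the labels. The antibodies in the selection kit and the stain used for purity are not given in the sources used here.

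The authors deposited 1 log2 value per probe set and array, made with oligo and RMA per the submitters' processing notes, which give no versions. RMA corrects background, sets the arrays to a common distribution and summarises the probes of a probe set. The log base is not stated in the labels and was taken from RMA and from the range of the values. Quantile scaling fixes each array's overall distribution, so a fall in the values of some genes can come from a rise of many others in the same RNA. Array medians over all probe sets lay between 7.83 and 7.93. The number of arrays limits the precision, and array values carry no count of molecules.

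The table held 35556 probe sets. The platform annotation gave 21789 of them 1 gene symbol and 1621 several symbols, and 12146 were unnamed here. Of the probe sets with 1 symbol, 21698 had an Entrez identifier in the RefSeq gene table of the mouse assembly GRCm38.p6, which changed 0 symbols. No genome build is named for the values, so no coordinates are given. The probe set with the highest mean over the 8 arrays stood for each gene, which left 19938 genes, 999 of them with more than 1 probe set. No filter on dim probe sets was applied. Probe sets with several symbols were left out of the gene tests. Some members of the fixed lists, the globin genes among them, are not analysed here, and some items are not reported here.

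The groups were taken from the labels. No array date, batch or pairing is given in the sources used here. Pregnant and non-pregnant arrays were compared with limma's lmFit and eBayes (two-sided) on the deposited log2 values, without covariates, and called at a Benjamini-Hochberg adjusted p under 0.05. Errors of single genes are limma's moderated standard errors, and errors of list means are standard errors from the 4 and 4 array means. Fixed lists of genes were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, over the 52 of 55 lists with at least 5 measured genes. The fry test of limma asks whether a list's genes move on balance 1 way, without comparing them with other genes. List means per array were compared with a two-sided exact permutation test, for which 4 against 4 arrays allow no p below 0.0286. The design, the gene lists, the rule for naming genes and the alternatives were set before the data were examined, except where stated.

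The named genes are the 10 with the largest positive and the 10 with the largest negative difference among those called, up to 4 members with the smallest p of each list described, and a fixed set, of which 15 were analysed, of genes of B cell receptor signalling, antibody secretion, hormone response, division and erythroid cells. Gene models, clone names, pseudogenes, small RNAs and antigen receptor segments were left out of the first part; leaving out clone names and pseudogenes went slightly beyond the rule as first written. Further genes were chosen after their values were seen and are named so that a list's count can be read. A second list of haem synthesis and red cell maturation genes and a second list of B cell genes were written after the first tests but before the values of their members were looked at.

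The steps were tested on simulated data with the residual spread of the 19938 genes and 200 genes shifted. In this simulation of pregnant against non-pregnant arrays, 83% of genes shifted by 0.5 and 95% of genes shifted by 1 (log2) were recovered, and 12 of 190 calls fell on unshifted genes. Noise was drawn independently for each gene and only 200 genes were shifted, whereas limma called 34.1% of genes in the data. These shares need not hold for the real comparison. Alternatives covered the scaling between arrays (array medians, quantile scaling again, centring on housekeeping genes), a filter on dim probe sets, the mean of a gene's probe sets, every probe set on its own, the variance model, array weights, mouse number, the erythroid list mean or the mean of other cell type lists as a covariate, each array left out, the threshold and the list test. Centring on the pan-B list was added after the fall of that list was seen. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.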

Results

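The transcriptomes of splenic B cell preparations were compared between 4 mice on day 14 of pregnancy and 4 non-pregnant mice, to ask how B cell gene expression differs during pregnancy. Expression of 19938 named genes was measured as log2 RMA values on 1 array per mouse. Across genes, which are not independent replicates, arrays of the same group correlated at 0.991 to 0.996 and arrays of different groups at 0.964 to 0.984. The first principal component held 76.3% of the variance and parted the groups, with pregnant arrays at −30.1 to −18.0 and non-pregnant arrays at 16.4 to 34.6. The array of non-pregnant mouse 81 and that of pregnant mouse 86 lay nearest to the other group.

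Genes of red blood cell formation and of cell division rose most in the pregnant preparations, while genes that define B cells and carry B cell receptor signals fell by a smaller amount. Rhag, the Rh-associated glycoprotein of the red cell membrane, rose by 3.30 ± 0.27 (log2, SE, n = 4 and 4; 9.88-fold), and the division marker Mki67 rose by 1.90 ± 0.10 (3.73-fold). Pax5, the transcription factor that maintains B cell identity, fell by 0.88, and Syk, the kinase that starts B cell receptor signalling, fell by 0.67. In all, 2983 genes were higher and 3814 lower in pregnant mice by limma, or 34.1% of those tested. Of the genes called by limma, 522 were higher and 0 lower by at least 2-fold, and 8659 genes had an unadjusted p under 0.05. The median difference was 0.50 among genes called higher and −0.32 among genes called lower.

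The groups did not overlap for 2789 genes higher and 3794 lower, 33.0% of genes, where chance gives 2.86%. Of the calls, 43.9% were higher, and 23.8% were when each array was centred on housekeeping genes. With the erythroid list mean of each array as a covariate, of whose variance 97.0% lay between the groups, limma called 0 genes and 1046 had an unadjusted p under 0.05. Of 140 named genes called without it, 96 kept their sign there, 29 of them with a difference at least as large, such as Jchain at 2.64 ± 1.14, and the median SE rose from 0.09 to 0.46.

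**Figure D1:**
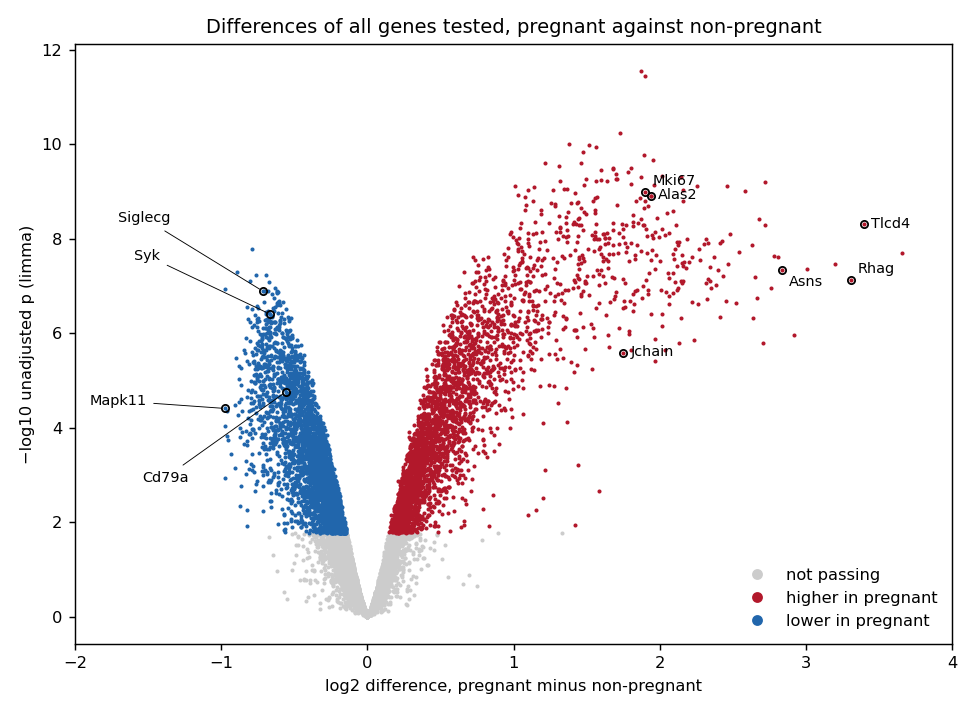
Each point is 1 of 19938 genes, with the log2 difference of pregnant minus non-pregnant arrays on the horizontal axis and minus log10 of limma's unadjusted p on the vertical axis. The 2983 genes called higher reach beyond 3 on the log2 scale, while the 3814 called lower stay above −1.

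The 10 largest rises among the named genes were Tlcd4, Rhag, Cldn13, Pkhd1l1, Tspan8, Asns, Rhd, Aldh1a1, Kel and Epb42. They ran from 3.39 ± 0.21 for Tlcd4 (10.5-fold, adjusted p = 9.9e-07) to 2.72 ± 0.17 for Epb42 (6.60-fold, adjusted p = 9.9e-07). Rhd and Kel encode blood group antigens and Epb42 a protein of the red cell membrane skeleton. Asns, the enzyme that makes asparagine, rose by 2.83 ± 0.22, and Aldh1a1, which makes retinoic acid, by 2.78 ± 0.20. The 10 largest falls were Mapk11, Trp53i11, Myadm, Stk10, Acsf2, Klf2, Ncr1, Fam102a, Prkd2 and Fmnl1. They ran from −0.98 ± 0.15 for Mapk11, a p38 kinase (1.97-fold, adjusted p = 0.00039), to −0.90 ± 0.20 for Fmnl1, a formin that shapes actin (1.87-fold, adjusted p = 0.0039). Klf2, which restrains activation of resting lymphocytes, fell by 0.96 ± 0.15. The call of Trp53i11 was lost with mouse number as a covariate, where its difference was −0.41. Of the variance of mouse number, 42.8% lay between the groups, so fits with it leave less of the group difference to estimate.

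Of 23 measured erythroid genes, 22 rose, and 23 did when adjusted over the list alone. The list mean was 10.79 ± 0.09 (SD, n = 4) in pregnant and 8.75 ± 0.28 in non-pregnant arrays, a difference of 2.04 ± 0.15 (camera adjusted p = 1.6e-26, adjusted p = 0.11 with an estimated correlation). Aqp1, a water channel of red cells, rose by 2.58 ± 0.14, Ank1 by 1.96 ± 0.10, Alas2, the first enzyme of haem synthesis in erythroid cells, by 1.94 ± 0.11, and Add2 by 1.73 ± 0.07. The brightest members in pregnant arrays were Car1 at 13.91, which rose by 0.97, Car2 at 13.57, which rose by 2.13, and Ermap at 12.27, which rose by 2.27. Of the 23 genes, 16 lay above the median of all values in the non-pregnant arrays too. Per array, the list mean ran from 10.71 to 10.91 in pregnant mice and from 8.43 to 9.11 in non-pregnant mice, with the highest of these in mouse 81.

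Cell division genes moved with the erythroid list, whose mean was higher by 2.04. All 22 measured mitosis genes rose, also when adjusted over the list alone, with a list difference of 1.91 ± 0.14 (camera adjusted p = 1.6e-26, adjusted p = 0.12 with an estimated correlation). Besides Mki67, the spindle genes Tpx2, Aurka and Bub1b rose by 2.09 ± 0.12, 1.56 ± 0.09 and 1.52 ± 0.07. Of 20 DNA replication genes, 19 rose, also when adjusted over the list alone (list difference 1.54 ± 0.09, camera adjusted p = 9e-24, adjusted p = 0.11 with an estimated correlation). They included the helicase subunits Mcm2 (1.48 ± 0.07) and Mcm3 (1.31 ± 0.06) and Uhrf1 (1.60 ± 0.08). Of 30 histone genes, 22 rose by either adjustment, over all genes or adjusted over the list alone, such as H2bc9 by 1.27 and H2bc18 by 1.15 (list difference 0.80 ± 0.08, camera adjusted p = 2.3e-13, adjusted p = 0.11 with an estimated correlation). With the erythroid list mean as a covariate, the calls of the mitosis list (0.30) and of the histone list (0.44) were lost, and the DNA replication list passed at 0.42.

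Genes of MYC-driven growth and of oxidative phosphorylation also rose, beside the erythroid rise of 2.04. Of 19 MYC-driven growth genes, which serve ribosome assembly and nucleotide and polyamine synthesis, 17 rose and 19 did when adjusted over the list alone. The list difference was 0.54 ± 0.03 (camera adjusted p = 9.1e-12), and this was the only list still past the threshold with an estimated correlation (adjusted p = 0.019). Odc1, which starts polyamine synthesis, rose by 1.36 ± 0.09, and the nucleolar genes Nop58 and Nolc1 rose by 0.86 and 0.77. Of 73 oxidative phosphorylation genes, 67 rose and 68 did when adjusted over the list alone, among them Sdhd (0.87), Ndufv1 (0.76) and Uqcrq (0.68). That list rose by 0.53 ± 0.08 (camera adjusted p = 1.1e-27, adjusted p = 0.21 with an estimated correlation). Of 11 heat shock genes, 4 rose by either adjustment, over all genes or adjusted over the list alone, including the mitochondrial chaperone Hspd1 (0.92) and Hsp90aa1 (0.60). The heat shock list difference was 0.27 ± 0.08 (camera adjusted p = 0.0061, adjusted p = 0.32 with an estimated correlation).

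Cytosolic ribosomal proteins changed little. Of 61 members, 10 rose and 1 fell, and 4 rose and 0 fell when adjusted over the list alone. The list mean was higher by 0.10 ± 0.04 (camera adjusted p = 0.00062, adjusted p = 0.43 with an estimated correlation), and that call was lost at 0.04 with mouse number as a covariate and the difference turned to −0.21 with the erythroid covariate. Rps27l rose by 1.35 and Rps2 by 0.28. In the unfolded protein response list, 6 of 24 genes rose and 2 fell, and 6 rose and 4 fell when adjusted over the list alone. Asns and Creld2 (0.66) rose, while the chaperone Hspa5 differed by 0.06. That list did not pass (mean difference 0.17 ± 0.03, camera adjusted p = 0.059), but passed without mouse 70 (0.20), without mouse 82 (0.19), without mouse 88 (0.17) and with mouse number as a covariate (0.19).

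**Figure D2:**
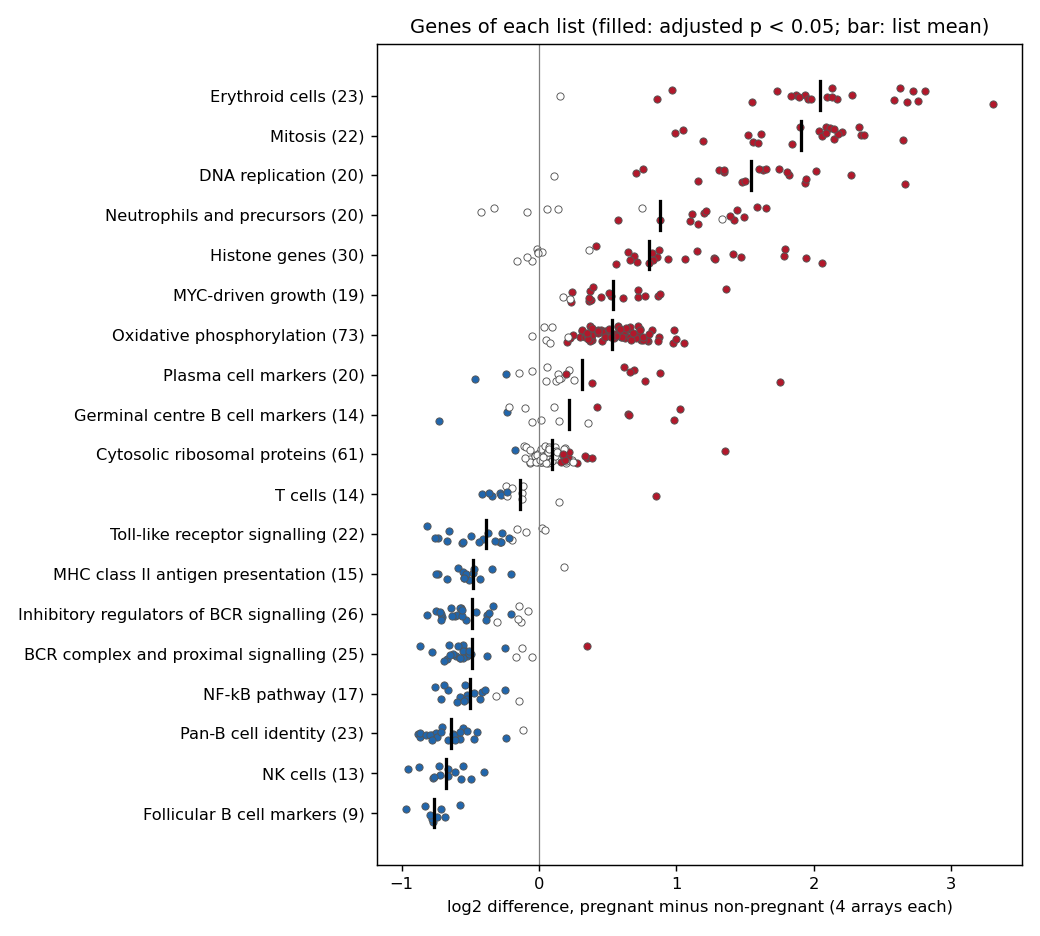
Each point is a gene of the list named on the vertical axis, with the number of measured members in parentheses, at its log2 difference of pregnant minus non-pregnant arrays; filled points passed adjusted p 0.05 and bars are list means. Erythroid and mitosis genes lie near 2 and the pan-B and follicular lists at −0.64 and −0.76; with arrays centred on the pan-B list, the lower lists shown lay above 0 apart from the NK list at −0.03 and the follicular list at −0.12.

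Genes that define the B cell lineage fell together as the erythroid list rose by 2.04. Of 23 pan-B genes, 22 fell, also when adjusted over the list alone, and the remaining gene, Tcf3, differed by −0.12. The list mean was 11.72 ± 0.14 (SD, n = 4) in pregnant and 12.36 ± 0.12 in non-pregnant arrays, a difference of −0.64 ± 0.09 (camera adjusted p = 1.2e-10, adjusted p = 0.27 with an estimated correlation). The kinase Blk fell by 0.78 ± 0.08, the co-receptor Cd72 by 0.71 ± 0.07, Fcrla by 0.62 and the adaptor Bank1 by 0.58. All 9 follicular B cell markers fell, also when adjusted over the list alone, by 0.76 ± 0.10 on average (camera adjusted p = 6.6e-06, adjusted p = 0.25 with an estimated correlation). They included the low-affinity IgE receptor Fcer2a (−0.83), the homing receptor Ccr7 (−0.78) and Zfp318 (−0.68). Of 13 marginal zone markers, 10 fell by either adjustment, over all genes or adjusted over the list alone, including S1pr1 (−0.80), Myof (−0.58) and the complement receptor Cr2 (−0.55). The marginal zone list fell by 0.45 ± 0.05 (camera adjusted p = 0.00045, adjusted p = 0.21 with an estimated correlation).

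B cell receptor signalling genes fell, both activating and inhibitory, beside an erythroid rise of 2.04 and a pan-B fall of 0.64. Of 25 genes of the receptor complex and its proximal signalling, 21 fell and 1 rose, by either adjustment, over all genes or adjusted over the list alone (list difference −0.49 ± 0.05, camera adjusted p = 1e-08, adjusted p = 0.21 with an estimated correlation). The receptor chains Cd79a and Cd79b fell by 0.56 ± 0.08 and 0.52 ± 0.06, the adaptor Blnk by 0.60 ± 0.06, the kinase Btk by 0.49 ± 0.06 and the phospholipase Plcg2 by 0.69 ± 0.11. Ighm, the heavy chain of IgM, rose by 0.35 ± 0.08 (adjusted p = 0.0056), a call lost at 0.23 when the mean of its probe sets was used. Of 24 genes of the downstream calcium, MAPK and NFAT branches, 16 fell by either adjustment, over all genes or adjusted over the list alone, including Rasgrp1 (−0.68), Malt1 (−0.67) and Itpr2 (−0.56). That list fell by 0.35 ± 0.07 (camera adjusted p = 5.2e-05, adjusted p = 0.30 with an estimated correlation). Of 26 inhibitory regulators, 21 fell and 22 did when adjusted over the list alone (list difference −0.49 ± 0.05, camera adjusted p = 2e-08, adjusted p = 0.21 with an estimated correlation). The inhibitory receptors Siglecg, Cd22 and Fcgr2b fell by 0.72 ± 0.06, 0.71 ± 0.09 and 0.53 ± 0.06, and the lipid kinase Dgka by 0.81 ± 0.08.

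The falls of these lists were compared with that of the pan-B list within each array, a test chosen after the falls were seen, over 55 lists including the second lists. Centring on the pan-B list raised the median difference of all genes by 0.64. On that scale the proximal signalling list, without its pan-B members, lay at 0.18 (95% interval 0.08 to 0.28), the downstream list at 0.29 (0.23 to 0.36) and the NF-kB list at 0.14 (0.06 to 0.22). For each of these the exact permutation p was 0.0286, the smallest possible, and 0.0349 after adjustment. The inhibitory list lay at 0.17 (0.02 to 0.33, exact permutation p = 0.0571, adjusted 0.0593), and the second list of other B cell genes at 0.14 (−0.01 to 0.28, exact permutation p = 0.0571, adjusted 0.0593), so the signalling lists lay near other B cell genes; a difference between them was not tested. The follicular list lay at −0.12 (−0.19 to −0.05, exact permutation p = 0.0286, adjusted 0.0349), the only list whose interval lay below 0.

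Activation and signalling genes downstream of several receptors were lower, with the pan-B list at −0.64 and the erythroid list at 2.04. Of 17 NF-kB pathway genes, 15 fell and 17 did when adjusted over the list alone, including Rel (−0.71), Ikbkb (−0.60) and Birc3 (−0.52). The NF-kB list fell by 0.50 ± 0.09 (camera adjusted p = 1.1e-06, adjusted p = 0.27 with an estimated correlation). Of 24 immediate early and activation genes, 18 fell and 2 rose, and 20 fell and 3 rose when adjusted over the list alone. Zfp36, Klf6, Dusp2 and Btg2 fell by 0.84, 0.83, 0.79 and 0.62, while Myc rose by 0.36 (list difference −0.46 ± 0.10, camera adjusted p = 0.00018, adjusted p = 0.39 with an estimated correlation). Of 22 Toll-like receptor signalling genes, 16 fell and 19 did when adjusted over the list alone, among them Irak3 (−0.67), Tlr1 (−0.66) and Ly86 (−0.49). The Toll-like receptor list fell by 0.39 ± 0.03 (camera adjusted p = 7.7e-06, adjusted p = 0.11 with an estimated correlation).

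Antigen presentation genes fell, again with the pan-B list at −0.64. Of 15 MHC class II genes, 14 fell, and 14 fell and 1 rose when adjusted over the list alone (list difference −0.48 ± 0.05, camera adjusted p = 1.3e-06, adjusted p = 0.25 with an estimated correlation). H2-Ob and H2-Oa, which restrain peptide loading, fell by 0.73 and 0.55, and the protease Ctss by 0.48. Of 15 MHC class I genes, 11 fell and 2 rose by either adjustment, over all genes or adjusted over the list alone. H2-Q4, H2-M3 and the peptide transporter Tap1 fell by 0.68, 0.64 and 0.50, and the chaperone Canx rose by 0.40. The class I list fell by 0.27 ± 0.05 (camera adjusted p = 0.027, adjusted p = 0.36 with an estimated correlation). Of 18 costimulation genes, 12 fell and 1 rose, and 13 fell and 1 rose when adjusted over the list alone. Slamf6 and Cd40 fell by 0.58 and 0.54, whereas Tnfrsf14, the receptor also known as HVEM, rose by 0.93 ± 0.09. The costimulation list fell by 0.31 ± 0.01 (camera adjusted p = 0.00075, adjusted p = 0.11 with an estimated correlation).

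Homing, cytokine and survival genes were lower in the same preparations, in which the erythroid list was higher by 2.04. Of 18 chemokine receptor and homing genes, 13 fell and 1 rose, and 14 fell and 1 rose when adjusted over the list alone. S1pr1, Ccr7 and Gpr183, which guide B cells within lymphoid tissue, fell by 0.80, 0.78 and 0.63 (list difference −0.43 ± 0.05, camera adjusted p = 2e-04, adjusted p = 0.21 with an estimated correlation). Of 22 cytokine and chemokine genes, 10 fell and 12 did when adjusted over the list alone, including Ccl5 (−0.87), Ltb (−0.84) and Lta (−0.57). That list fell by 0.32 ± 0.08 (camera adjusted p = 0.0073, adjusted p = 0.27 with an estimated correlation), and Il10 differed by 0.13 ± 0.06 (adjusted p = 0.14), passing at 0.18 after quantile scaling again. Of 13 B-1 cell markers, 9 fell and 1 rose, and 10 fell and 1 rose when adjusted over the list alone, including Il5ra (−0.65) and Bhlhe40 (−0.64). The B-1 list fell by 0.29 ± 0.05 (camera adjusted p = 0.024, adjusted p = 0.27 with an estimated correlation), a call lost at −0.21 with mouse number and at −0.029 with the erythroid list mean as a covariate. Of 7 anti-apoptotic genes, 5 fell by either adjustment, over all genes or adjusted over the list alone, including Bcl2 (−0.80) and Birc3 (−0.52). The anti-apoptotic call (−0.35 ± 0.02, camera adjusted p = 0.045, adjusted p = 0.23 with an estimated correlation) was lost without mouse 81 (−0.36), without mouse 86 (−0.35) and under 5 other settings (−0.43 to −0.28).

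Genes of antibody secretion went the other way from the pan-B list. Of 20 plasma cell markers, 8 rose and 2 fell, and 9 rose and 2 fell when adjusted over the list alone (list difference 0.31 ± 0.05, camera adjusted p = 0.00016, adjusted p = 0.27 with an estimated correlation). Jchain, which joins IgM and IgA into polymers, rose by 1.75 ± 0.20 (3.36-fold, adjusted p = 5.2e-05). Ell2, the BCMA gene Tnfrsf17 and Txndc5 rose by 0.77, 0.69 and 0.62. Prdm1, the master regulator of plasma cells, differed by 0.16 ± 0.08 (adjusted p = 0.17), passing at 0.31 with mouse number as a covariate, and Irf4 fell by 0.46. Of 8 immunoglobulin variable segments with a probe set of their own, 4 rose by either adjustment, over all genes or adjusted over the list alone, including Igkv4-55 (1.37) and Igkv8-30 (0.65). The variable segment call (0.41 ± 0.08, camera adjusted p = 0.030, adjusted p = 0.27 with an estimated correlation) was lost without mouse 70 (0.38), mouse 81 (0.40) or mouse 90 (0.37) and under 4 other settings (0.32 to 0.80). Igkv8-30 lost its call at 0.27 with mouse number as a covariate.

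Germinal centre markers were mixed. Of 14 genes, 5 rose and 2 fell, and 6 rose and 2 fell when adjusted over the list alone. The methyltransferase gene Ezh2 rose by 1.03, Mybl1 by 0.99 and Nuggc by 0.42, while Bcl6, the regulator of the germinal centre programme, fell by 0.73. Ezh2 and Mybl1 are also active in dividing cells of other lineages. The list mean was higher by 0.22 ± 0.07 (camera adjusted p = 0.048, adjusted p = 0.36 with an estimated correlation). This call was lost without mouse 70 (0.19), mouse 76 (0.18), mouse 81 (0.21), mouse 82 (0.21) or mouse 90 (0.19) and under 4 other settings (0.15 to 0.24), and the list lay at −0.023 with dim probe sets left out. Of 14 genes of the immature and early B lineage, 2 rose and 4 fell by either adjustment, over all genes or adjusted over the list alone, with Myb at 0.76, Cd24a at 0.46, Vpreb3 at −0.77 and Lef1 at −0.40 (list difference −0.06 ± 0.04, camera adjusted p = 0.85).

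Markers of other blood cells moved in different directions. All 13 NK cell genes fell, also when adjusted over the list alone, by 0.67 ± 0.17 on average (camera adjusted p = 0.00012, adjusted p = 0.36 with an estimated correlation). The receptor gene Ncr1 fell by 0.95 ± 0.17, the granzymes Gzma and Gzmb by 0.87 and 0.77, and Tbx21 by 0.50. Of 20 genes of neutrophils and their precursors, 13 rose and 14 did when adjusted over the list alone (list difference 0.88 ± 0.38, camera adjusted p = 9.7e-07, adjusted p = 0.30 with an estimated correlation). The granule genes Mpo, Prtn3 and Ctsg rose by 1.65, 1.49 and 1.11 and Ms4a3 by 0.88, while Csf3r and Cxcr2, receptors of mature neutrophils, differed by −0.42 and −0.33 without passing. By the exact permutation test, the neutrophil list mean did not part the groups (p = 0.0857, n = 4 and 4). Of 14 T cell genes, 6 fell and 1 rose, and 7 fell and 1 rose when adjusted over the list alone (list difference −0.14 ± 0.08, camera adjusted p = 0.21). Zap70 and Cd247 fell by 0.36 and 0.28, the latter call being lost at −0.23 with mouse number as a covariate, and Ubash3a rose by 0.85.

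Monocyte and macrophage genes did not shift as a list (−0.04 ± 0.13, camera adjusted p = 0.86). Of 19 members, 2 rose and 2 fell by either adjustment, over all genes or adjusted over the list alone, including the iron exporter Slc40a1 (1.97) and Apoe (−0.49). Of 11 genes of basophils, mast cells and eosinophils, 3 rose by either adjustment, over all genes or adjusted over the list alone, including Prg2 (0.90) and Mcpt8 (0.47). That list rose by 0.23 ± 0.05 (camera adjusted p = 0.032, adjusted p = 0.21 with an estimated correlation), a call lost at 0.22 without mouse 90, at 0.34 with dim probe sets left out and at 0.23 with the erythroid covariate. Of 10 stem and progenitor genes, Kit (1.16) and Cd34 (0.33) rose, also when adjusted over the list alone, with a list mean of 0.15 ± 0.04, a median of −0.01 and a camera adjusted p of 0.21. The Cd34 call was lost without mouse 76 (0.25), mouse 82 (0.32), mouse 88 (0.29) or mouse 90 (0.30), with arrays centred on housekeeping genes (0.25) and with mouse number as a covariate (0.23), and it turned to −0.55 with the erythroid covariate.

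**Figure D3:**
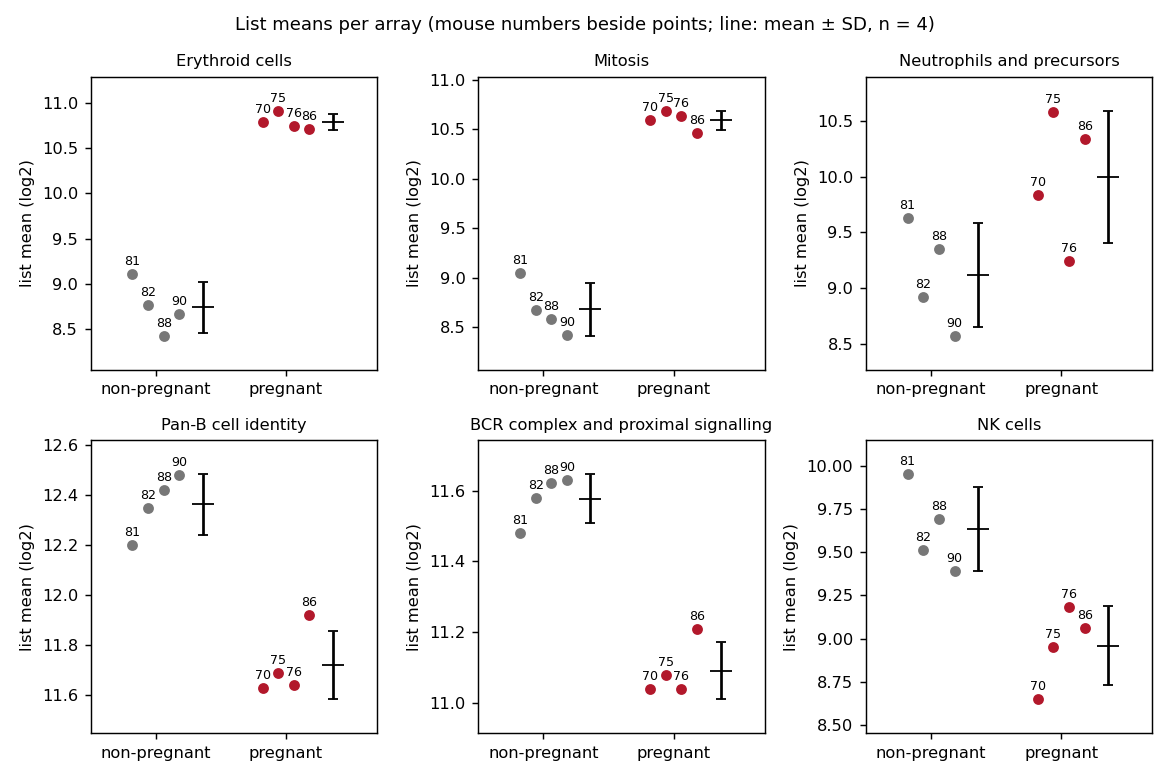
Points are the mean log2 value of a list on each array, with the mouse number beside it and the group mean ± SD (n = 4) at the right of each group. The 4 pregnant arrays lie above the 4 non-pregnant arrays for the erythroid and mitosis lists and below them for the pan-B, B cell receptor and NK lists, while the neutrophil list overlaps between groups. With arrays centred on the pan-B list, the 21 B cell receptor genes outside that list were higher by 0.18 and the NK list lower by 0.03 in pregnant arrays.

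Hormone receptor and hormone response genes shifted in both directions. Of 12 receptors of steroid, prolactin and growth hormones, 2 rose and 2 fell, and 2 rose and 5 fell when adjusted over the list alone (list difference −0.04 ± 0.03, camera adjusted p = 0.85). The glucocorticoid receptor Nr3c1 fell by 0.30 ± 0.06 (adjusted p = 0.0016) and the oestrogen receptor Esr1 by 0.26. The membrane progesterone-binding proteins Pgrmc1 and Pgrmc2 rose by 0.56 and 0.21, and the Pgrmc2 call was lost without mouse 70 (0.18), mouse 75 (0.21), mouse 81 (0.17), mouse 86 (0.19) or mouse 88 (0.20) and under 5 other settings (0.13 to 0.49). Of 19 glucocorticoid-induced genes, 3 rose and 11 fell, and 3 rose and 12 fell when adjusted over the list alone. The metallothioneins Mt2 and Mt1 rose by 1.34 and 1.30, while Sgk1 and Nfkbia fell by 0.61 and 0.52 (list difference −0.14 ± 0.05, camera adjusted p = 0.16).

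Interferon and regulatory lists did not pass. Of 30 type I interferon genes, 7 rose and 9 fell, and 8 rose and 9 fell when adjusted over the list alone (list difference 0.06 ± 0.05, camera adjusted p = 0.31, and −0.023 with arrays centred on housekeeping genes). Ifih1, Rsad2 and Cmpk2 rose by 1.10, 0.90 and 0.78, and Ddx58 fell by 0.39. Of 13 interferon gamma genes, 7 fell and 1 rose by either adjustment, over all genes or adjusted over the list alone, including Ciita (−0.75) and Cd274 (−0.45), and the list (−0.23 ± 0.03, camera adjusted p = 0.084) passed without mouse 90 (−0.24), with dim probe sets left out (−0.30) and with mouse number as a covariate (−0.19). Of 15 genes of regulatory B cells, 6 fell by either adjustment, over all genes or adjusted over the list alone, such as Cd1d1 (−0.53), with a list difference of −0.18 ± 0.02 (camera adjusted p = 0.21). Of 10 receptors and ligands of the BAFF and TNF families, 6 fell and 1 rose, and 7 fell and 1 rose when adjusted over the list alone (−0.24 ± 0.07, camera adjusted p = 0.099). That list passed without mouse 75 (−0.28), after quantile scaling again (−0.25) and with dim probe sets left out (−0.40).

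Of 52 lists tested, 30 passed with the preset correlation, 13 higher and 17 lower. With an estimated correlation only the MYC-driven growth list did, and fry called 39 lists at its adjusted p under 0.05. The remaining lists, which covered glycolysis, hypoxia, cholesterol synthesis, STAT5 targets, cell death, small nucleolar RNAs, dendritic cells, platelets, stroma and housekeeping genes, had mean differences from −0.16 to 0.08 and did not pass. Among them, the small nucleolar RNA list passed with mouse number (−0.20) or the erythroid list mean (−0.68) as a covariate and the housekeeping list after quantile scaling again (0.11). For the STAT5 target and cholesterol synthesis lists, the mean was below 0 while camera gave the direction as up, and for the glycolysis and stem cell lists the mean and the median differed in sign.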

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

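The tests of scaling, of dividing B cells, of signalling relative to the pan-B list, of NK genes and of bright genes of other cell types were chosen after the results they bear on were seen; the second lists and the splits of the arrays were set before. Single arrays stood apart from the other 3 of their group, by the gap to the nearest array as a share of the group's range, in 16 of 390 tests, fewer than the 1 in 20 that chance gives. In pregnant mice this held for Syk (0.939, mouse 86), Blnk (0.938, mouse 70), Rps2 (0.913, mouse 70), Ell2 (0.858, mouse 86), Igkv4-55 (0.865, mouse 70), Apoe (0.955, mouse 70), Mt2 (0.838, mouse 75) and the follicular list (0.852, mouse 86). In non-pregnant mice it held for Cd79b (0.952, mouse 81), Hspd1 (0.835, mouse 90), Cd40 (0.959, mouse 90), Klf6 (0.855, mouse 88), Gpr183 (0.838, mouse 82), Nuggc (0.836, mouse 90), the T cell list (0.840, mouse 90) and the conventional dendritic cell list (0.871, mouse 88). The widest such gap was that of Igkv4-55, at 11.71 in mouse 70 against 12.64 to 12.79 in the other pregnant mice. Among the 12146 unnamed probe sets, which no gene comparison used, 2411 passed limma's adjusted p of 0.05, 678 higher and 1733 lower.

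Erythroid and cell division genes were higher in pregnant preparations. The erythroid difference was at least 1.96 under every scaling set beforehand, so it does not hinge on the choice among these scalings. They moved the median difference of all genes by only −0.080 to 0.033, too little to remove the rise, so they do not decide on scaling. A shift common to all genes of an array would move every list alike. The erythroid list rose by 2.68 relative to the pan-B list (95% interval 2.15 to 3.22), while the median gene differed by −0.069. These values argue against such a shift as the cause of the erythroid rise. Scaling that acts unevenly over genes is not covered by them. RNA of erythroid precursors in the pregnant preparations is a candidate explanation. A second list of haem and red cell genes was higher by 0.89, with 17 of 19 genes up and 1 down. Car1 and Car2 reached 13.91 and 13.57 in pregnant arrays. Of 23 erythroid genes, 16 lay above the median of all values in non-pregnant arrays too, so such signal was not confined to pregnant mice. However, the labels give negative selection and a purity above 98% by flow cytometry. Whether these cover erythroid precursors is not given in the sources used here, and the globins were not analysed here. More dividing B cells could add to the cell division genes, but the test of it is weak: the germinal centre list lay 0.86 above the pan-B list (95% interval 0.52 to 1.20), where the median of all genes lay at 0.57 and the mitosis list at 2.55, and its own difference was 0.22, or −0.023 with dim probe sets left out, with Ezh2 and Mybl1 active in other dividing cells too. These sources cannot be told apart for the division genes in bulk RNA, and pregnancy itself as a cause of either stays open.

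B cell genes were lower in pregnant preparations. The pan-B difference was −0.61 or lower under every scaling set beforehand, but these scalings moved the median gene too little to decide on scaling as a cause. A shift common to all genes of an array is argued against, as housekeeping genes lay 0.72 above the pan-B list (95% interval 0.55 to 0.89). As a list, the B cell receptor genes outside the pan-B list lay at 0.18 (95% interval 0.08 to 0.28) relative to it. That argues against a larger fall of their list mean only. The follicular list was the only list whose interval lay below 0 on that scale. A value above 0 is thus not particular to receptor genes and cannot exclude a fall of them within B cells. The second list of B cell genes lay at 0.14 and the median gene at 0.57 on that scale. A fall of receptor genes beyond that of the second list was not tested. Dilution by erythroid RNA may account for part of the fall, since a second list of B cell genes fell by 0.50, with 17 of 18 genes lower, but a fall of B cell transcripts would give this too, and by arithmetic the pan-B fall would need 35.8% less B cell RNA in the total. Genes of other cell types above the median of all values lay 0.87 above the pan-B list (95% interval 0.41 to 1.32), or 0.61 without neutrophils. Dimmer genes, also without neutrophils, lay at 0.62 and the median gene at 0.57. The value of the brighter genes thus does not set them apart from the rest of the array and cannot decide on dilution. Bright conventional dendritic genes lay at 0.29 (−0.06 to 0.64). The MHC class II list, at 0.16, lay near the second list of B cell genes, at 0.14. The follicular list lay at −0.12 (−0.19 to −0.05) on that scale. Members of the pan-B list themselves differed unevenly, from −0.88 to −0.12, so this value cannot decide on dilution alone. A fall of B cell transcripts during pregnancy stays open, since the preparations were not counted by cell.

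NK cell genes fell while erythroid genes rose. A lower share of B cells that raised every other cell type alike is argued against, as the interval of the NK list ended at −0.27. Equal dilution of all other RNA by erythroid RNA would put the NK list near the pan-B list, and it lay at −0.03 relative to it (−0.54 to 0.48). Genes above the median of all values in the other cell type lists lay 0.87 above the pan-B list (0.41 to 1.32), or 0.61 (0.30 to 0.92) without neutrophils. Dimmer genes without neutrophils lay at 0.62 and the median gene at 0.57, so the brighter genes cannot decide on dilution. Equal dilution, dilution beside a rise of other cell types, fewer NK cells in the preparations and a fall of NK transcripts stay open, given that interval and 4 arrays per group.

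Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many higher genes (2983, highest other 0). The real split was also the only 1 to give as many lower genes (3814, highest other 0). That share, 2.9%, is the smallest that 35 splits allow, so it argues against chance for both counts without excluding it. Every other split mixes the groups, so a difference between the groups widens the spread within each side of that split and lowers its calls. The splits cannot tell such a difference from a batch that followed the groups. No array date or batch is given, so such a batch was not tested. For the lists, 3 of 35 splits gave at least as many calls as the real 30, with 33 as the highest other, so chance is not excluded for the number of lists called with the preset correlation.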

How the results depend on the processing

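Centring on the pan-B list was added after the data were seen; all other settings were chosen beforehand. No paired analysis was possible because the groups share no replicate numbers. Leaving out each array in turn gave 2625 to 3033 higher genes, 2894 to 3946 lower genes and 27 to 31 lists. Genes called lower numbered 7804 with arrays centred on housekeeping genes (23.8% of calls higher, against 43.9%) and 2314 with mouse number as a covariate. Mouse number is partly tied to the groups, with 42.8% of its variance between them. With a change of at least 1.5-fold, 1221 higher and 496 lower genes passed the adjusted p and 1224 and 497 the unadjusted p, fewer by construction. With every probe set tested on its own, the counts of genes higher in pregnant and genes lower in pregnant became 3993 and 5311 probe sets. The lists called fell to 1 when camera used an estimated correlation. Centring on the pan-B list raised the median difference of all genes by 0.64 and gave 18571 genes higher and 20 lower (99.9% higher), with 30 lists; 2584 genes called in the uncentred comparison were then called in the opposite direction. The germinal centre list lay at −0.023 with dim probe sets left out; the cause was not tested.

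With the erythroid list mean as a covariate, limma called 0 higher and 0 lower genes (1046 at an unadjusted p under 0.05) and camera 13 lists. Of that covariate's variance 97.0% lay between the groups, so this fit leaves little of the group difference to estimate, and the cause of single reversals was not tested. Of the named genes called without it, those that changed sign lay, below 0, at Tlcd4 −0.35, Rhag −1.52, Cldn13 −1.10, Pkhd1l1 −0.82, Tspan8 −1.82, Asns −0.78, Rhd −0.83, Aldh1a1 −0.54, Kel −1.42, Epb42 −0.11, Sdhd −0.042, Rps27l −0.36, Tnfrsf14 −0.077, Igkv4-55 −0.29, Ctsg −0.39, Ms4a3 −0.059, Mpo −0.20, Mcpt8 −0.065, Kit −0.56, Cd34 −0.55, Mt2 −1.37, Mt1 −1.21, and, above 0, at Mapk11 0.33, Trp53i11 1.62, Stk10 0.72, Acsf2 1.13, Klf2 1.05, Fam102a 1.45, Prkd2 0.68, Fmnl1 1.46, Cd79a 0.043, Plcg2 0.44, Rel 0.28, H2-Q4 0.21, Tap1 0.027, Zfp36 0.11, Btg2 0.17, Dusp2 0.35, Bhlhe40 0.29, Lta 0.12, Ltb 1.03, Bcl2 0.046, Sgk1 0.29, Ciita 0.018. The list means that changed sign included Oxidative phosphorylation −0.15, Cytosolic ribosomal proteins −0.21, Pan-B cell identity 0.16, BCR complex and proximal signalling 0.013, BCR downstream calcium, MAPK and NFAT branches 0.29, NF-kB pathway 0.37, MHC class I antigen presentation 0.21, Immediate early and activation genes 0.68, Chemokine receptors and homing 0.068, Follicular B cell markers 0.15, Neutrophils and precursors −0.94, STAT5 target genes 0.67, Cholesterol biosynthesis 1.35, Megakaryocytes and platelets −1.32; 10 further lists that did not pass moved to the other side of 0, such as the pro-apoptotic (0.26), hypoxia (0.26), type I interferon (−0.18), glucocorticoid (0.14) and stem cell (−0.12) lists. Lists that kept their sign but lost their call there were mitosis (0.30), histone genes (0.44), inhibitory regulators (−0.24), MHC class II (−0.054), Toll-like receptor signalling (−0.15), marginal zone (−0.17), B-1 (−0.029), cytokines (−0.19), anti-apoptotic genes (−0.28), immunoglobulin variable segments (0.80) and basophils (0.23). The erythroid list itself has no value in that fit, whose covariate it is. Under the scaling, filter, probe set, variance, weight, mouse number and other cell type settings, no named gene changed sign after passing. With single arrays left out, named genes kept their direction and side of the threshold in 1127 tests and lost their call in 9, and lists did so in 393, lost it in 11, gained it in 5 and, without passing, changed sign in 7. Arrays carry no depth, and signal over background limits dim genes: 10152 genes were left by the filter at the median of all values on at least 4 arrays.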

Other observations

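The lists in this part and their tests were fixed beforehand, and the genes named from them were picked after their values were seen. Glycolysis genes went both ways in pregnant preparations. Of 17 measured, 5 rose and 4 fell by limma, also when adjusted over the list alone, with the muscle-type phosphofructokinase gene Pfkm at 1.32, Tpi1 at 0.68, the glucose transporter gene Slc2a1 at −0.78 and Pfkp at −0.43. The list mean was 0.06 ± 0.07 and its median −0.05 (camera adjusted p = 0.34), and the mean lay at −0.024 with arrays centred on housekeeping genes. Of 21 hypoxia response genes, 6 rose and 7 fell, and 6 rose and 9 fell when adjusted over the list alone, with Ero1a at 0.59 and Higd1a at 0.58 against Pfkfb3 at −0.43 (list mean −0.07 ± 0.04, camera adjusted p = 0.92). Of 17 cholesterol synthesis genes, 4 rose and 2 fell, also when adjusted over the list alone, with Sqle at 0.58 and Srebf2, the transcription factor of the pathway, at −0.69 (list mean −0.02 ± 0.11, camera adjusted p = 0.73).

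Pro-apoptotic genes were mostly not passing, with 4 of 14 lower, among them Bmf at −0.50 and Casp8 at −0.36 (list mean −0.09 ± 0.03, camera adjusted p = 0.57). Among 3 measured immunoglobulin constant regions, Ighm rose, and Ighg3 and Igha differed by 0.34 and 0.25 without passing. The integrin chain Itgb1 rose by 0.84 while 13 other homing genes fell. Of 12 housekeeping genes, 6 rose and 3 fell, with Hprt at 0.72 and Polr2a at −0.50, and 7 rose and 3 fell when adjusted over the list alone (list mean 0.08 ± 0.03, camera adjusted p = 0.099).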
